A study of Homo sapiens with 28 samples.

How the data were processed

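Expression was measured by poly(A) RNA sequencing in THP-1 macrophages and SUM159 cells. Per the labels, total RNA was purified on columns with DNase, made into stranded mRNA libraries and read on an Illumina HiSeq instrument. The deposited values were estimated counts (expected counts per gene symbol, not normalized), and the submitters' processing notes name bcl2fastq, Salmon, DESeq2 and the build GRCh38 without versions. Their description says that the counts were taken from tximport. The annotation release and whether strand was used in counting are not given in the sources used here, so genes with antisense or overlapping neighbours, pseudogenes and close paralogs (HSPA6, HSPA1B, MTRNR2L8, FTH1P2) have uncertain counts. The sample titles of the knockdown experiment read as a knockout while the treatment label gives an siRNA against MLX, and the latter was used.

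The 3 tables held 35187 genes each. Of these, 27 carried symbols that read as calendar dates, a change that spreadsheet software makes, and they held 0.1028%, 0.1726% and 0.132% of the counts in the siRNA, knockout and acLDL tables. They were kept in library totals and were not named. Values with a fractional part made up 31%, 38.8% and 47% of entries and were rounded to whole counts. No library was left out. Each experiment was sequenced in a single lane per its titles, and no batch is given in the labels.

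Counts were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests after TMM normalization, with 1 model per experiment that held a mean for each group. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16877 genes in the acLDL, 15198 in the siRNA and 14410 in the knockout experiment. p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The 11 comparisons were acLDL against none, siMLX against control at each glucose level, 25 against 0 mM glucose in each siRNA background, knockout against wild type at each glucose level, glucose in each SUM159 line, and the interaction in each of the 2 designs. The common biological coefficient of variation (BCV) was 0.043 in the acLDL, 0.313 in the siRNA and 0.092 in the knockout experiment, so the siRNA experiment could call only larger changes.

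For 24 lists of genes written from general knowledge, covering lipid, sugar, stress, signalling and cell type markers, members were counted over all genes tested and with p-values adjusted over the list alone. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on a preset correlation of 0.01 between genes, and again with the correlation estimated from the libraries. Overlaps of calls between comparisons that share no library used one-sided Fisher's exact tests over genes tested in both, and the numbers shared by independent lists are products of the margins. Comparisons, lists, tests and the rule for naming genes were fixed before the data were examined. The rule named MLX, TXNIP and ARRDC4, the 6 genes with the largest change in each direction among called genes with a mean of at least 5 CPM and groups that did not overlap, and up to 4 members with the smallest adjusted p per list. The overlap condition was not set for interactions. Members of lists that are only counted were left out, and genes outside the rule are said to have been chosen after their values were seen.

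Among the named genes called, the libraries of the groups did not overlap for 32 of 32 with acLDL, 12 of 12 and 21 of 21 with siMLX at 0 and 25 mM, 24 of 24 and 8 of 8 with glucose in control and siMLX macrophages, 19 of 19 and 20 of 20 in knockout cells, and 5 of 5 and 4 of 4 with glucose in WT and KO cells. The rule asks for this of the largest changes, and list members were picked for a small adjusted p, so these counts are no support for the calls. Among genes not so picked, chance gives it to 10% at 3 against 3 and 33.3% at 2 against 2. MRC1, GNLY, NKG7 and TGFBI with acLDL are not in these counts.

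Alternatives chosen beforehand were DESeq2 1.42.0, median-of-ratios size factors (RLE) in edgeR, no filter on low counts, the replicate number as a block, only the 6 libraries compared, and leaving out each library in turn. limma voom with library quality weights, and a correction for each library's trend over GC content and transcript length (splines with 5 degrees of freedom, fitted on genes at 5 CPM or more), were chosen after seeing the data. Chance was looked at by refitting all 10 splits of 3 against 3 libraries, and 100 drawn arrangements for each interaction. The tests were tried on simulated data with planted changes in the libraries of 3 comparisons. Changes of 2-fold and 4-fold were recovered for 80.8% and 100% of planted genes with acLDL, 48% and 72.9% with siMLX at 25 mM, and 72.7% and 93.9% in KO cells at 25 mM. False calls were 12.8%, 7.1% and 7.3% of calls, above the nominal 5% in each, so calls near the threshold are less sure than their adjusted p. With a strong trend over GC content also planted in 1 group, false calls numbered 8116, 1526 and 5932, and 23, 4 and 11 after the GC correction, so the shares above hold only without such a trend. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures. A gene's fold against a group at 0 counts was taken against 3 counts per library. CPM are counts over TMM-scaled library totals.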

Results

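RNA was measured by poly(A) RNA sequencing in 28 libraries of human cell lines, from 3 experiments with 10 groups. THP-1 is a monocytic leukaemia line that phorbol ester turns into macrophage-like cells, and SUM159 is a breast carcinoma line. In the first experiment, THP-1 macrophages were kept without acetylated LDL (acLDL, a modified lipoprotein that macrophages take up and store as lipid droplets; n = 2) or with acLDL at 50 µg/mL for 2 days (n = 2). Per the labels, both groups were differentiated for 1 day with phorbol ester at 50 nM. No later time is given for cells without acLDL, so time since differentiation may differ between the groups. In the second, THP-1 macrophages received an siRNA against MLX (siMLX) or the RISC-free control siRNA and were kept at 0 or 25 mM glucose (n = 3 per group). These were differentiated for 2 days, and no phorbol ester dose is given. In the third, wild type (WT) and MLX knockout (KO) SUM159 cells were kept at 0 or 25 mM glucose (n = 3 per group). Library totals were 40.7 to 54.2 M (mega) counts in the acLDL experiment, 8.0 to 12.3 M in the siRNA experiment and 18.0 to 24.9 M in SUM159. A gene with 3 counts in a library stood at 0.055 to 0.074 CPM (a library's counts scaled to a common total) in the acLDL experiment, at 0.244 to 0.373 CPM in the siRNA experiment and at 0.12 to 0.166 CPM in SUM159, and these floors cover counting error only. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these libraries. Values with ± are means and SD of CPM. Those of log2 fold changes are approximate standard errors, the absolute log2 fold change over the square root of its F statistic.

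The targeted gene was looked at first. MLX lies on chromosome 17 (42567068 to 42573239, + strand, GRCh38) and encodes the dimer partner through which the glucose-sensing factors MondoA and ChREBP bind DNA. In THP-1 cells at 0 mM glucose, MLX stood at 105 ± 7.46 CPM with the control siRNA and 10.3 ± 8.0 CPM with siMLX (10.1-fold lower, adjusted p = 5.08e-05). The siMLX libraries at 0 mM were uneven, at 19.5, 5.22 and 6.10 CPM, and without siMLX 0 mM replicate 1 the log2 fold change was −4.21 in place of −3.34. At 25 mM, MLX fell from 106 ± 4.51 to 19.4 ± 1.22 CPM (5.48-fold, adjusted p = 0.000397). In SUM159 cells, the knockout lowered MLX from 55.6 ± 1.22 to 15.1 ± 0.737 CPM at 0 mM (3.68-fold, adjusted p = 1.26e-10), and from 53.96 ± 0.934 to 13.48 ± 0.3 CPM at 25 mM (4-fold, adjusted p = 6.75e-11). Transcript thus remained in the knockout cells. By edgeR no change of MLX with glucose was called in any of the 4 backgrounds (adjusted p = 0.976 in RISC-free, 0.0616 in siMLX, 0.807 in WT and 0.0659 in KO). In siMLX cells the log2 fold change of 0.91 was called with quality weights (1.06, adjusted p = 0.042), with the GC correction (0.91, adjusted p = 0.0472) and without siMLX 0 mM replicate 1 (1.78, adjusted p = 2.9e-06). acLDL raised MLX 1.19-fold (adjusted p = 0.000959).

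**Figure D1:**
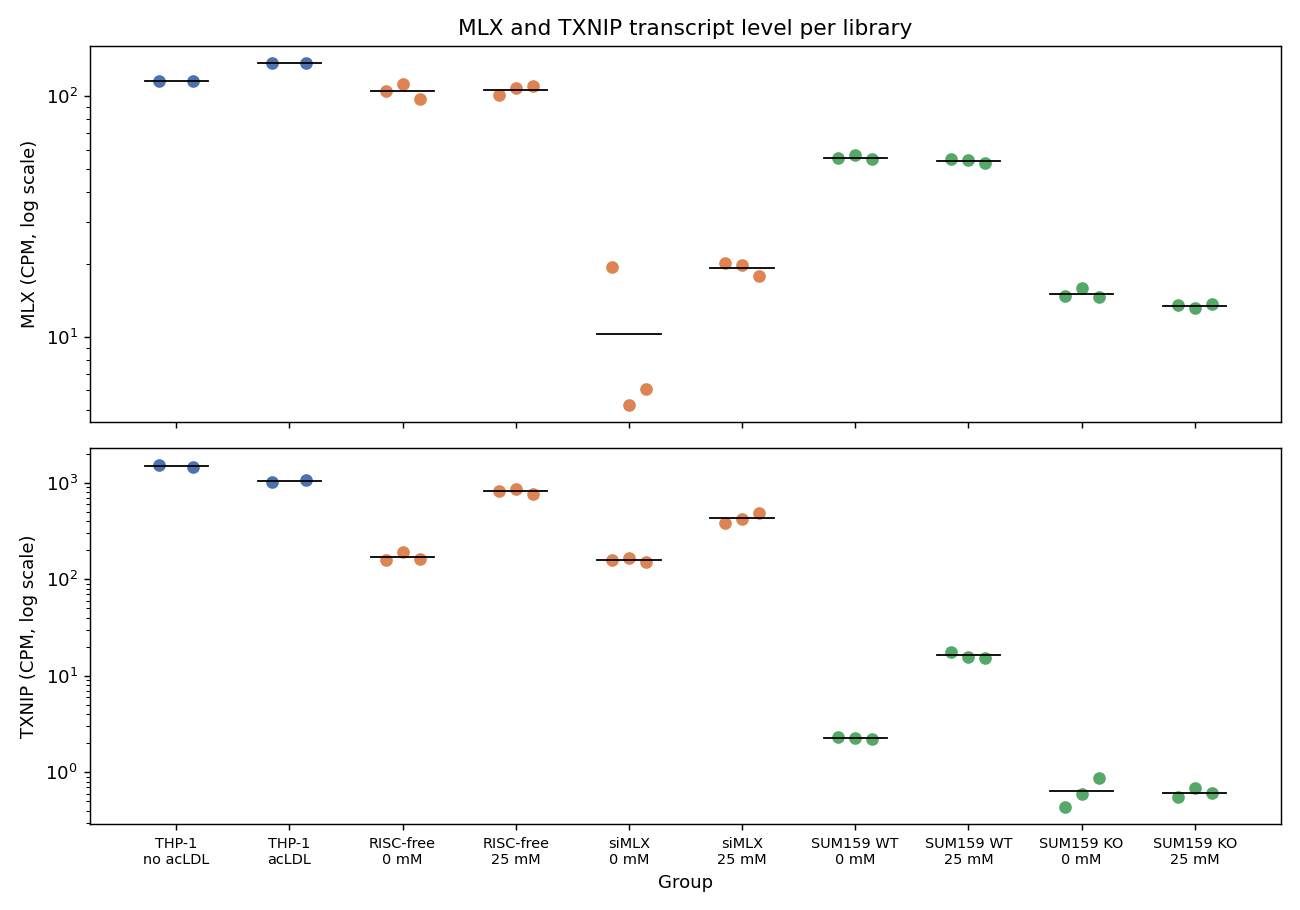
MLX (upper panel) and TXNIP (lower panel) in CPM on log axes, 1 point per library, with a line at each group's mean, for the 10 groups. MLX fell from 105 to 10.3 CPM at 0 mM and from 106 to 19.4 CPM at 25 mM with siMLX, and TXNIP stood at 16.3 CPM in WT SUM159 cells at 25 mM against 0.615 CPM in KO cells.

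The comparison of THP-1 macrophages with and without acLDL asked how lipid loading changes their transcriptome. CCL20, a chemokine for lymphocytes and dendritic cells, went from 9.21 ± 0.388 to 641 ± 41.1 CPM (69.5-fold, adjusted p = 8.82e-13, n = 2 against 2). CXCL8, the neutrophil chemokine, rose 56.3-fold and IL1B 11.8-fold. MSMO1, an enzyme of cholesterol synthesis, fell 3.06-fold. Fatty acid desaturases also fell, FADS2 by 10.3-fold (adjusted p = 2.83e-11) and SCD by 2.27-fold. Among lipid storage genes PLIN2, which coats lipid droplets, doubled (2.01-fold, 708 ± 6.81 against 353 ± 15.8 CPM), and the triglyceride synthesis enzymes GPAT3 and DGAT2 rose 3.79-fold and 3.26-fold. LIPA, the lysosomal acid lipase that frees cholesterol from lipoprotein, fell 2.23-fold (adjusted p = 8.67e-09).

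Of 16877 genes tested, 3443 were higher and 3480 lower with acLDL, and 704 of the higher and 576 of the lower ones moved at least 2-fold. In the list of NF-kB and inflammatory cytokine genes, 17 of 19 tested rose, 0 fell and 2 were not called (camera adjusted p = 1.51e-70, adjusted p = 0.0552 with an estimated correlation). Where a count adjusted over the list alone is not given, here and later, it was the same as the count over all genes tested. All 25 cell cycle and proliferation genes fell, with a median log2 fold change of −1.41 and MKI67, TOP2A and TYMS lower by 3.61-, 3.62- and 3.96-fold (camera adjusted p = 6.59e-42, adjusted p = 0.0699 with an estimated correlation). Of 24 genes of cholesterol synthesis and uptake, 23 fell and 1 rose (median log2 fold change −0.95, camera adjusted p = 5.4e-39, adjusted p = 0.0552 with an estimated correlation). Of 14 genes of fatty acid synthesis and desaturation 12 fell and 2 rose (9.21e-13, 0.07 with an estimated correlation). Among 18 LXR targets, the genes that oxysterols switch on to export cholesterol, 10 rose, 5 fell and 3 were not called (camera adjusted p = 9.82e-05, adjusted p = 0.127 with an estimated correlation), APOE rising 2.49-fold and SMPDL3A 3.25-fold. The lipid droplet and triglyceride list had 10 genes higher, 3 lower and 11 not called of 24 (0.000426, 0.133 with an estimated correlation).

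Stress and signalling genes also moved with acLDL. In the hypoxia list 13 of 16 rose, 1 fell and 2 were not called, and 14 rose when adjusted over the list alone. VEGFA rose 3.6-fold and NDRG1 2.52-fold (camera adjusted p = 9.21e-13, adjusted p = 0.07 with an estimated correlation). Immediate early genes, the first transcripts induced by growth signals, had 15 of 19 higher, 2 lower and 2 not called, with EGR1 3.91-fold and EGR3 13.9-fold higher (3.19e-13, 0.07 with an estimated correlation). The ATF4 and amino acid list had 17 of 26 higher, 0 lower and 9 not called, among them DDIT4 (2.33-fold) and SLC7A11 (2.23-fold; camera adjusted p = 2.23e-07, adjusted p = 0.113 with an estimated correlation). Endoplasmic reticulum chaperones had 16 of 20 higher, 0 lower and 4 not called (2.74e-05, 0.154 with an estimated correlation). Lysosome genes had 18 of 25 higher, 1 lower and 6 not called, or 19 and 1 adjusted over the list alone (2.74e-05, 0.154 with an estimated correlation). Glycolysis genes had 12 of 22 higher, 1 lower and 9 not called, or 13 and 1 adjusted over the list alone (0.000527, 0.154 with an estimated correlation). The lysosomal cholesterol exporter NPC1 and the protease CTSL each rose 2.56-fold, in contrast to LIPA. All 13 mitochondrially encoded genes rose (2.93e-05, 0.127 with an estimated correlation). In contrast, 18 of 21 ribosome biogenesis genes fell, 0 rose and 3 were not called, or 19 fell adjusted over the list alone (0.000222, 0.154 with an estimated correlation). Interferon-stimulated genes had 2 of 24 higher, 12 lower and 10 not called, with IFIT1 2.12-fold lower (0.0114, 0.331 with an estimated correlation).

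The targets of ChREBP and MondoA split with acLDL. RGS16 rose 7.32-fold and ARRDC3 1.89-fold, while TXNIP, which restrains glucose uptake, fell 1.45-fold (1033 ± 31.7 against 1497 ± 34.2 CPM, adjusted p = 2.16e-06) and its relative ARRDC4 fell 1.68-fold (adjusted p = 1.56e-06). The list had 8 genes higher, 6 lower and 1 not called of 15, with a camera adjusted p of 0.0285 (0.188 with an estimated correlation). This became 0.141 without no-acLDL replicate 1 and 0.0775 without no-acLDL replicate 2. In the list of the MLX family and the MYC network, 5 of 15 rose, 5 fell and 5 were not called (camera adjusted p = 0.183). The repressor gene MXD1 rose 2.84-fold and MYC fell 1.93-fold, and the median (−0.02) and the mean (0.19) of its log2 fold changes differed in sign. Macrophage markers had 9 genes higher and 7 lower of 16 (0.777), with CD14 4.54-fold higher and CYBB 2.38-fold lower. MRC1 of this list fell 15.9-fold (0.828 ± 0.0175 against 13.2 ± 0.235 CPM, adjusted p = 8.33e-10), the largest fall among genes open to naming. Here too the median (0.18) and the mean (−0.14) log2 fold change of the list differed in sign. No shift was called for the pentose phosphate list (7 higher and 2 lower of 14, 0.174) or PPAR targets (6 higher and 6 lower of 19, 0.962). The same held for nuclear-encoded oxidative phosphorylation (1 higher and 7 lower of 23, 0.149) and p53 targets (3 higher and 5 lower of 16, 0.995). All 18 list calls by camera were lost when the correlation between genes was estimated from these libraries, 2 per group.

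The siRNA comparison at 0 mM glucose asked what loss of MLX does in macrophages without glucose. No group received a differently labelled siRNA against MLX. Effects of siMLX other than on MLX therefore cannot be told apart from loss of MLX, here and later. PLIN2 rose 1.7-fold with siMLX (699 ± 70.1 against 411 ± 19.5 CPM, adjusted p = 0.000573, n = 3 against 3), and LIPA fell 2.84-fold (244 ± 18.1 against 694 ± 72.1 CPM, adjusted p = 2.55e-05). The lysosomal protease CTSL rose 1.44-fold. CTGF, a matrix-associated growth factor gene, rose 2.94-fold (adjusted p = 0.00265), the neuropeptide gene NMB fell 4.54-fold (adjusted p = 9.77e-05) and NES, an intermediate filament gene, fell 4.43-fold. TXNIP did not change (log2 fold change −0.09, adjusted p = 0.808), nor did ARRDC4 (adjusted p = 0.446).

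With siMLX at 0 mM, 97 genes were higher and 361 lower of 15198 tested, 19 and 102 of them by at least 2-fold. DESeq2 gave 206 and 547, and higher counts were 191 with quality weights and 272 with the GC correction. Without RISC-free 0 mM replicates 1, 2 and 3 there were 63, 52 and 43 higher and 240, 238 and 211 lower, and without siMLX 0 mM replicates 1 and 3 there were 53 and 59 higher. Interferon-stimulated genes had 6 of 24 higher, 0 lower and 18 not called, or 10 higher adjusted over the list alone (camera adjusted p = 3.57e-10, 0.221 with an estimated correlation). OASL led it, at 1.94-fold (adjusted p = 0.000313). Endoplasmic reticulum chaperones had 3 of 20 lower and 17 not called, or 10 lower and 1 higher adjusted over the list alone, HYOU1 being 1.37-fold lower (0.000131, 0.0743 with an estimated correlation). PPAR targets and fatty acid oxidation genes had 2 of 19 higher, PLIN2 and FABP4, and 17 not called, or 3 higher adjusted over the list alone (0.000936, 0.0743 with an estimated correlation). FABP4 rose 1.72-fold, a call lost without RISC-free 0 mM replicate 1 (adjusted p = 0.11) or 3 (0.0973) or siMLX 0 mM replicate 2 (0.0968). Ribosome biogenesis genes had a median log2 fold change of 0.24 with 0 of 21 called (camera adjusted p = 0.00106, adjusted p = 0.221 with an estimated correlation). Of the 25 lysosome genes 3 rose and 4 fell (0.329), and of the 15 macrophage markers 1 rose and 3 fell (0.233), the integrin ITGAM by 1.93-fold. Glycolysis had 2 of 22 lower, or 3 adjusted over the list alone (0.0403, and 0.271 with an estimated correlation), and immediate early genes 2 of 20, or 5 adjusted over the list alone (0.0403, and 0.304 with an estimated correlation). Cholesterol genes had 4 of 24 lower, or 5 adjusted over the list alone (0.0495, and 0.212 with an estimated correlation). None of the 3 calls survived every left-out library. After correction for GC content and length, glycolysis stood at 0.067 and immediate early genes at 0.0823. Glycolysis stood at 0.0516 without RISC-free 0 mM replicate 3, 0.057 without siMLX 0 mM replicate 1 and 0.0525 without siMLX 0 mM replicate 3. Immediate early genes stood at 0.081 and 0.0534 without RISC-free 0 mM replicates 1 and 2 and at 0.335 without siMLX 0 mM replicate 2. Cholesterol genes stood at 0.0985 and 0.0516 without RISC-free 0 mM replicates 2 and 3 and at 0.0805, 0.103 and 0.0525 without siMLX 0 mM replicates 1, 2 and 3.

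At 25 mM glucose the same comparison asked what loss of MLX does when its partners are supplied with glucose. TXNIP fell 1.89-fold with siMLX (432 ± 55.3 against 817 ± 42.7 CPM, adjusted p = 0.000114, n = 3 against 3). So did RGS16 (1.65-fold, adjusted p = 0.00443) and KLF10 (1.84-fold, adjusted p = 0.00927), other targets of the glucose-sensing factors. FABP4, the fatty acid carrier of macrophages, rose 2.06-fold (273 ± 25.5 against 132 ± 24.4 CPM, adjusted p = 0.00284). PLIN2 rose 1.5-fold (adjusted p = 0.0068) but was not called without RISC-free 25 mM replicate 2 (log2 fold change 0.50, adjusted p = 0.0525). LIPA fell 2.31-fold (adjusted p = 0.000114) and NMB 6.13-fold (adjusted p = 2.49e-05). EGR1, an immediate early transcription factor, fell 2.54-fold (36.1 ± 4.96 against 91.7 ± 9.92 CPM, adjusted p = 0.000128). APOE, the lipoprotein that macrophages secrete, fell 1.67-fold (adjusted p = 0.00443).

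With siMLX at 25 mM, 56 genes were higher and 257 lower of 15198, 16 and 62 of them by at least 2-fold. DESeq2 gave 151 and 500, and higher counts were 100 with no filter, 131 with the GC correction and 27 with only the 6 libraries. Without RISC-free 25 mM replicates 1, 2 and 3 there were 30, 19 and 18 higher and 163, 159 and 155 lower. In 3 lists the shift was also called with an estimated correlation. ChREBP and MondoA targets had 3 of 15 lower and 12 not called, or 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000125, 0.0431 with an estimated correlation). PPAR targets had 4 of 19 higher and 15 not called, or 7 higher adjusted over the list alone (1.28e-05, 0.0396 with an estimated correlation). Immediate early genes had 6 of 20 lower and 14 not called, or 8 adjusted over the list alone, with EGR2, JUN and DUSP6 lower by 1.62-, 1.58- and 1.39-fold (3e-08, 0.0431 with an estimated correlation). NF-kB and cytokine genes had 3 of 17 lower, or 4 adjusted over the list alone, including TNFAIP3 and NFKBIA, each 1.82-fold (0.000314, 0.107 with an estimated correlation). Glycolysis had 3 of 22 lower, or 5 adjusted over the list alone, PKM by 1.41-fold, SLC2A1 by 1.48-fold and HK2 by 1.64-fold (0.000535, 0.0949 with an estimated correlation). Lower shifts were called with the preset correlation alone for the cell cycle list (1 of 25 lower, or 2 adjusted over the list alone; 0.000535, 0.166 with an estimated correlation) and for macrophage markers (3 of 15, or 6 adjusted over the list alone; 0.00121, 0.0508 with an estimated correlation). The same held for p53 targets (3 of 15, GDF15 and CDKN1A lower by 1.76- and 1.41-fold; 0.00572, 0.0585 with an estimated correlation). The MLX family had 2 of 15 lower (or 4 adjusted over the list alone; 0.0098, 0.0585 with an estimated correlation) and stood at 0.151 after correction for GC content and length. MLX, which the siRNA itself lowers, belongs to this family, and the list's mean log2 fold change (−0.30) lay below its median (−0.14). The shift is therefore not read as a response of the network.

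Further calls at 25 mM were lost on leaving out any of several libraries. The hypoxia list had 3 of 16 lower, and 1 higher adjusted over the list alone, with VEGFA 1.68-fold and NDRG1 1.88-fold lower, while its median (0.08) and mean (0.01) were above 0 (camera adjusted p = 0.0336, 0.209 with an estimated correlation). It stood at 0.126, 0.0572, 0.0797 and 0.163 without RISC-free 25 mM replicates 1 and 2 and siMLX 25 mM replicates 1 and 2. Lysosome genes had 4 of 25 lower, and 1 higher adjusted over the list alone (0.0336, 0.09 with an estimated correlation), and the call was lost without RISC-free 25 mM replicate 1 (0.0584) or 2 (0.0531) or siMLX 25 mM replicate 1 (0.0797). Endoplasmic reticulum chaperones had 1 of 20 higher and 2 lower, or 1 and 3 adjusted over the list alone (0.0377, 0.143 with an estimated correlation), lost without RISC-free 25 mM replicate 1 (0.133) or siMLX 25 mM replicate 1 (0.0797). Mitochondrially encoded genes shifted up with 0 of 13 called (0.0377, 0.603 with an estimated correlation), lost without RISC-free 25 mM replicate 1 (0.146) or siMLX 25 mM replicate 3 (0.677) and with RLE size factors (0.0566) or the GC correction (0.413). Interferon-stimulated genes, higher at 0 mM, were not called at 25 mM (0 of 24, or 1 lower adjusted over the list alone, median log2 fold change −0.07, 0.11), nor were ribosome biogenesis genes (0 of 21, 0.11). ChREBP and MondoA targets were not called at 0 mM (1 of 15 lower, 0.57). The lipid droplet list did not shift at 0 mM (1 of 24 higher, 0.962) or at 25 mM (1 of 24 higher, 0.75). Nor did cholesterol genes at 25 mM (0 of 24 called, 0.422), fatty acid synthesis genes (2 of 14 lower, 0.0883 at 0 mM, and 0 of 14, or 4 lower adjusted over the list alone, 0.0845 at 25 mM) or LXR targets (2 of 17 lower, or 3 lower and 1 higher adjusted over the list alone, 0.303 at 0 mM, and 1 of 17 lower, 0.301 at 25 mM). Of the genes called at both glucose levels, 169 moved in the same direction (12 higher and 157 lower, where independent lists would share 0.357 and 6.1), and 288 by DESeq2. By edgeR 0 moved in opposite directions and by DESeq2 1, where 2.97 would by edgeR.

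**Figure D2:**
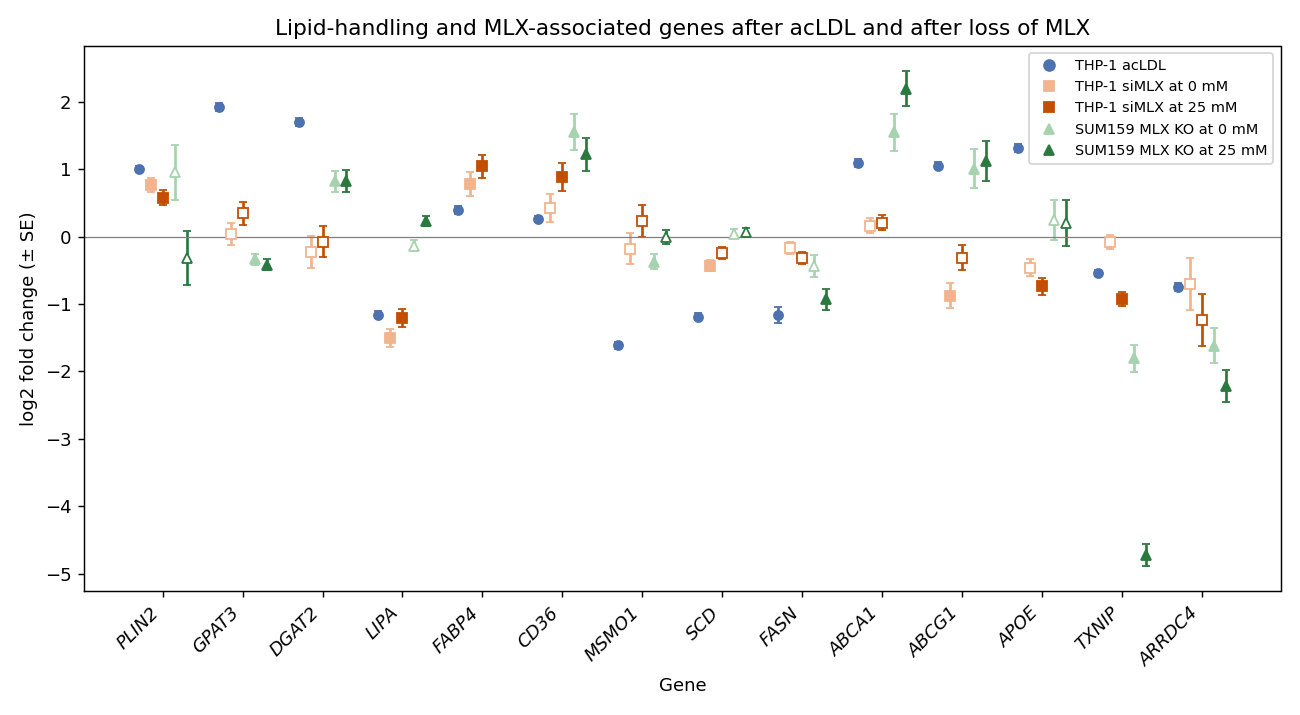
log2 fold change with its approximate standard error for 14 genes of lipid handling and MLX-associated regulation, after acLDL (n = 2 against 2) and after loss of MLX in THP-1 and SUM159 cells (n = 3 against 3). Filled symbols have an adjusted p below 0.05, and FABP4 is left out for SUM159, where WT cells had 3 counts or fewer. LIPA fell 2.84-fold with siMLX at 0 mM and 2.31-fold at 25 mM, and PLIN2 rose 1.7-fold and 1.5-fold.

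Glucose itself was compared in control macrophages, asking which genes 25 mM glucose changes against none. TXNIP rose 4.83-fold (817 ± 42.7 against 169 ± 17.9 CPM, adjusted p = 1.3e-10, n = 3 against 3). Genes of the unfolded protein response were far higher without glucose. HSPA5, the main endoplasmic reticulum chaperone, was at 11440 ± 345 CPM at 0 mM and 803 ± 70.2 CPM at 25 mM (14.2-fold lower, adjusted p = 5.91e-16). PDIA4 was 13-fold and HYOU1 11.9-fold lower. TRIB3, a target of the stress factor ATF4, was 13.7-fold lower with glucose, and the amino acid transporter genes SLC7A5 and SLC3A2 8.9-fold and 6.16-fold. HSPA6, a heat shock gene, was 215-fold lower (2.53 ± 1.31 against 526 ± 38.3 CPM). PLIN2 fell 1.75-fold with glucose (adjusted p = 2.76e-05), while FABP4 rose 3.08-fold, the desaturase FADS2 3.84-fold and the lipoprotein lipase gene LPL 3.24-fold.

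With glucose, 1643 genes were higher and 1749 lower in control macrophages, 558 and 810 of them by at least 2-fold. All 20 endoplasmic reticulum chaperone genes fell (median log2 fold change −2.70, camera adjusted p = 2.1e-170, 1.33e-07 with an estimated correlation). Of 26 ATF4 genes 24 fell and 1 rose (median −2.20, 3.96e-81, 1.7e-05 with an estimated correlation). Interferon-stimulated genes had 23 of 24 higher, or 24 adjusted over the list alone, with MX1 3.48-fold and RSAD2 3.63-fold higher (median 1.21, 1.1e-35, 0.0107 with an estimated correlation). Cell cycle genes had 17 of 25 higher and 8 not called, or 21 higher and 1 lower adjusted over the list alone, MCM2 rising 3.85-fold (median 1.69, 7.28e-14, 0.0155 with an estimated correlation). Shifts called with the preset and with an estimated correlation were also seen for the pentose phosphate list (7 of 14 lower; 3.78e-06, 0.0107) and hypoxia (8 of 16 lower, and 1 higher adjusted over the list alone; 3.78e-06, 0.0176). The same was true of macrophage markers (9 of 15 higher and 1 lower, or 10 and 1 adjusted over the list alone; 3.78e-06, 0.0107) and fatty acid synthesis (8 of 14 higher and 1 lower, or 9 and 1 adjusted over the list alone; 0.00023, 0.0124). Such shifts were called too for oxidative phosphorylation (11 of 23 higher, or 12 adjusted over the list alone; 0.000265, 0.0155) and LXR targets (5 of 17 higher and 3 lower, or 7 and 3 adjusted over the list alone; 0.00733, 0.0336). Among these, VEGFA fell 3.39-fold, IDH1 4.17-fold, and the scavenger receptor gene MSR1 rose 2.98-fold, SCD 1.92-fold and COX5B 1.98-fold.

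Other lists moved with glucose by the preset correlation alone in control macrophages. NF-kB genes had 11 of 17 higher and 1 lower, or 12 and 1 adjusted over the list alone, NFKBIA by 2.87-fold (4.6e-05, 0.0737 with an estimated correlation). Glycolysis had 12 of 22 higher and 3 lower, or 14 and 3 adjusted over the list alone, LDHA rising 3.08-fold and HK2 falling 2.72-fold (0.00124, 0.0882 with an estimated correlation). p53 targets had 2 of 15 higher and 5 lower, with GDF15 4.02-fold lower (0.0352, 0.082 with an estimated correlation). This call was lost without RISC-free 0 mM replicate 2 (0.0859) or RISC-free 25 mM replicate 2 (0.0654) or 3 (0.0564). The list of ChREBP and MondoA targets as a whole did not shift (4 of 15 higher and 3 lower, or 5 and 3 adjusted over the list alone, 0.185; median −0.16, mean 0.34), nor did lysosome genes (7 higher and 5 lower of 25, or 9 and 6 adjusted over the list alone, 0.321). No shift was called for cholesterol genes (6 higher and 5 lower of 24, 0.0639) or lipid droplet genes (1 higher and 4 lower of 24, or 2 and 4 adjusted over the list alone, 0.357). The same held for PPAR targets (4 higher and 4 lower of 19, or 4 and 5 adjusted over the list alone, 0.82) and mitochondrially encoded genes (0 of 13 called, 0.209).

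The same glucose comparison in siMLX macrophages asked whether the response remained when MLX was low. TXNIP rose 2.71-fold (432 ± 55.3 against 159 ± 8.19 CPM, adjusted p = 4.07e-08, n = 3 against 3). HSPA5 was 12.5-fold lower with glucose (1022 ± 49.7 against 12790 ± 174 CPM, adjusted p = 1.13e-15), TRIB3 11.6-fold and DDIT3, the stress factor CHOP, 17.5-fold. MKI67, a proliferation marker, rose 13.6-fold, and DTL, a replication licensing gene at 0 counts in all siMLX libraries at 0 mM, reached 15.89 CPM, at least 57.8-fold above the 3-count floor per library. FABP4 rose 3.71-fold and PLIN2 fell 1.99-fold (adjusted p = 3.9e-06).

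In siMLX macrophages 1511 genes were higher and 1497 lower with glucose, 492 and 680 of them by at least 2-fold. In all 2207 genes moved the same way in both siRNA backgrounds (1055 higher and 1152 lower, where 163 and 172 would be shared by independent lists) against 2 in opposite directions. All 20 chaperone genes fell (camera adjusted p = 7.29e-187, 3.86e-08 with an estimated correlation). Of 26 ATF4 genes 23 fell and 1 rose, or 24 and 1 adjusted over the list alone (3.32e-92; 1.22e-05). Further, 21 of 24 interferon-stimulated genes rose (8.73e-20; 0.0252) and 16 of 25 cell cycle genes rose and 1 fell, or 20 and 1 adjusted over the list alone (1.29e-12; 0.0178). Calls that held with an estimated correlation included hypoxia (8 of 16 lower, or 9 adjusted over the list alone; 2.88e-07, 0.0139) and fatty acid synthesis (7 of 14 higher and 1 lower, or 8 and 1 adjusted over the list alone; 6.8e-05, 0.0139). They also included oxidative phosphorylation (12 of 23 higher and 1 lower, or 15 and 1 adjusted over the list alone; 0.000122, 0.0139) and macrophage markers (8 of 15 higher and 2 lower, or 9 and 2 adjusted over the list alone; 7.66e-05, 0.0139). Held as well were the pentose phosphate list (6 of 14 lower; 0.000204, 0.0179) and LXR targets (6 of 17 higher and 2 lower, or 7 and 2 adjusted over the list alone; 0.00321, 0.0237). So were cholesterol genes (9 of 24 higher and 4 lower, or 10 and 4 adjusted over the list alone; 0.00485, 0.0237) and p53 targets (2 of 15 higher and 6 lower; 0.00491, 0.0328). Glycolysis (11 of 22 higher and 3 lower; 0.00321, 0.123 with an estimated correlation) and NF-kB genes (5 of 17 higher and 1 lower; 0.0353, 0.299 with an estimated correlation) were called with the preset correlation alone. The latter call was lost without siMLX 0 mM replicate 2 (0.0861) or siMLX 25 mM replicate 3 (0.143) and with the GC correction (0.0753).

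The interaction of siRNA and glucose tested whether siMLX changed the glucose response in macrophages. TXNIP responded 1.79-fold less with siMLX, short of the threshold by edgeR (adjusted p = 0.0545) and past it by DESeq2 (adjusted p = 3.88e-06), with RLE size factors (0.0411), with no filter (0.0035), with quality weights (0.00597) and with the GC correction (0.000773). It also passed without RISC-free 0 mM replicate 2 (0.0412) or siMLX 25 mM replicate 3 (0.0139). By edgeR 4 genes were higher and 2 lower, and the count at an unadjusted p under 0.05 was 1066. ADM2, a peptide hormone gene of the stress response, fell less with glucose in siMLX cells (interaction log2 fold change 1.62 ± 0.20, adjusted p = 0.00865). The heat shock gene HSPA1B also fell less (0.85 ± 0.14, adjusted p = 0.0468). In contrast, OASL (−1.02 ± 0.17, adjusted p = 0.0477) and the secreted phosphoprotein gene SPP1 (−0.51 ± 0.08, adjusted p = 0.0404) rose less. DTL (adjusted p = 0.0366) had 0 counts in 1 group, so its interaction has no fold, and these genes were chosen after their values were seen. The 6th gene is not given here. None of the 5 kept its call through every left-out library, and without RISC-free 25 mM replicate 1, 2 or 3 or siMLX 0 mM replicate 2 edgeR called 0 genes (888, 978, 1012 and 1364 at an unadjusted p under 0.05). By adjusted p, ADM2 stood at 0.0502, 0.0719 and 0.0583 without RISC-free 25 mM replicates 1, 2 and 3 and at 0.0503 without siMLX 0 mM replicate 2. HSPA1B stood at 0.139 and 0.159 without RISC-free 0 mM replicates 1 and 3 and at 0.0502, 0.138 and 0.0844 without RISC-free 25 mM replicates 1, 2 and 3. It stood at 0.133, 0.0893 and 0.116 without siMLX 0 mM replicates 1, 2 and 3 and at 0.147 and 0.12 without siMLX 25 mM replicates 1 and 2. OASL stood at 0.144, 0.149 and 0.159 without RISC-free 0 mM replicates 1, 2 and 3 and at 0.16, 0.175 and 0.0657 without RISC-free 25 mM replicates 1, 2 and 3. It stood at 0.172, 0.0893 and 0.168 without siMLX 0 mM replicates 1, 2 and 3 and at 0.147 and 0.0742 without siMLX 25 mM replicates 1 and 3. SPP1 stood at 0.0933 and 0.081 without RISC-free 0 mM replicates 1 and 2 and at 0.0502, 0.138 and 0.0799 without RISC-free 25 mM replicates 1, 2 and 3. It stood at 0.0813, 0.0893 and 0.116 without siMLX 0 mM replicates 1, 2 and 3 and at 0.147 and 0.0966 without siMLX 25 mM replicates 1 and 2. DTL stood at 0.0711, 0.138 and 0.0583 without RISC-free 25 mM replicates 1, 2 and 3 and at 0.0813, 0.0893 and 0.116 without siMLX 0 mM replicates 1, 2 and 3. It stood at 0.0899 and 0.0602 without siMLX 25 mM replicates 1 and 2. With quality weights ADM2 (0.173) and DTL (0.42) were not called. DESeq2 called 15 genes higher and 32 lower, and with no filter the counts were 9 and 12. Higher counts were 2 without RISC-free 0 mM replicate 3, siMLX 0 mM replicate 1 or siMLX 25 mM replicate 2, and 1 without siMLX 0 mM replicate 3 or siMLX 25 mM replicate 1. Lower counts were 1 without RISC-free 0 mM replicate 2 or 3 or siMLX 25 mM replicate 2. The genes lower with all libraries by edgeR were OASL and SPP1, whose left-out libraries stand above. Interferon-stimulated genes shifted down, with 1 of 24 lower, or 8 adjusted over the list alone (camera adjusted p = 2.79e-15, 0.198 with an estimated correlation). So did NF-kB genes (0 of 17 called, 4.55e-05, 0.198 with an estimated correlation) and ChREBP and MondoA targets (0 of 15 called, or 2 lower adjusted over the list alone; 0.00724, 0.198 with an estimated correlation, and 0.102 without siMLX 0 mM replicate 3).

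Wild type and MLX knockout SUM159 cells were compared at each glucose level to ask what loss of MLX does in a carcinoma line. TXNIP was 26.4-fold lower in KO cells at 25 mM (0.615 ± 0.0656 against 16.3 ± 1.18 CPM, adjusted p = 3.48e-10, n = 3 against 3) and 3.5-fold lower at 0 mM (adjusted p = 1.21e-05), and ARRDC4 was 4.65-fold and 3.06-fold lower. Genes nearly silent in WT cells were high in KO cells. NCAM1, a neural adhesion gene, was at 203 ± 14.2 against 0.731 ± 0.0611 CPM at 25 mM (275-fold) and 246-fold higher at 0 mM, and the collagen gene COL3A1 was 217-fold and 109-fold higher. The matrix protease gene MMP14 fell 6.27-fold and the actin-binding TAGLN 6.34-fold at 25 mM. Lipid genes moved both ways: CIDEC, which enlarges lipid droplets, rose 5.73-fold and the sterol exporter ABCA1 4.59-fold at 25 mM, while the fatty acid elongase gene ELOVL5 fell 1.55-fold.

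In KO cells 2452 genes were higher and 2398 lower at 0 mM (600 and 354 by at least 2-fold), and 3390 higher and 3579 lower at 25 mM (702 and 581 by at least 2-fold), of 14410 tested. The same direction was called at both levels for 3888 genes (1945 higher and 1943 lower, where 577 and 596 would be shared by independent lists), against 3 in opposite directions. Interferon-stimulated genes had 14 of 20 higher and 1 lower at 0 mM, or 15 and 2 adjusted over the list alone (median log2 fold change 1.14, camera adjusted p = 8.82e-15, 0.00129 with an estimated correlation). They had 13 higher and 1 lower at 25 mM (3.63e-12, 0.000954 with an estimated correlation). OASL was 8.44-fold and 7.37-fold and IFI44L 5.9-fold and 5.67-fold higher. No other list was called with an estimated correlation. The pentose phosphate and NADPH list had 10 of 14 lower at 0 mM, or 11 adjusted over the list alone (2.08e-05, 0.0939 with an estimated correlation). It had 13 lower and 1 higher at 25 mM (1.56e-05, 0.118 with an estimated correlation), where PGD and TALDO1 fell 1.65-fold and 1.72-fold. PPAR targets had 10 of 18 higher and 1 lower at both levels, or 11 and 1 adjusted over the list alone at 0 mM (0.000969 and 0.0111; 0.0939 and 0.201 with an estimated correlation), the oxidation enzyme ACADM rising 1.55-fold and 1.68-fold.

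Signalling and organelle lists moved in KO cells as well. Immediate early genes had 8 of 19 lower and 1 higher at 0 mM, or 8 and 2 adjusted over the list alone, and 11 lower and 1 higher at 25 mM, IER3 falling 3.1-fold and 3.72-fold (0.000969 and 3.06e-05; 0.3 and 0.211 with an estimated correlation). Hypoxia genes had 7 and 8 of 17 lower and 0 and 2 higher, or 9 lower and 1 higher adjusted over the list alone at 0 mM, with EGLN3 3.74-fold and 5.15-fold lower (0.000969 and 0.00819; 0.137 and 0.211 with an estimated correlation). Lysosome genes had 11 and 15 of 25 lower against 3 and 4 higher, or 12 and 3 adjusted over the list alone at 0 mM, with the sialidase gene NEU1 2.66-fold and 2.84-fold lower (0.00369 and 0.00236; 0.3 and 0.232 with an estimated correlation). Chaperones had 12 and 14 of 20 lower against 1 and 3 higher, or 13 and 2 adjusted over the list alone at 0 mM (0.00654 and 0.00233; 0.3 and 0.211 with an estimated correlation). Mitochondrially encoded genes had 7 and 13 of 13 higher, and 9 adjusted over the list alone at 0 mM, MT-CYB by 1.81-fold and 2.15-fold (0.019 and 2.89e-05; 0.683 and 0.439 with an estimated correlation). Oxidative phosphorylation genes had 14 of 23 higher at 0 mM, or 16 adjusted over the list alone (0.000264, 0.343 with an estimated correlation). They had 11 higher and 1 lower at 25 mM (0.0133, 0.56 with an estimated correlation), the latter lost without KO 25 mM replicate 1 (0.0934) and with the GC correction (0.064). The ChREBP and MondoA list did not shift at 0 mM (3 higher and 4 lower of 14, or 4 and 5 adjusted over the list alone, 0.654) or 25 mM (4 higher and 7 lower, 0.115). At 25 mM glycolysis (6 higher and 13 lower of 22, 0.115) and cholesterol genes (1 higher and 10 lower of 24, 0.14) did not shift either. Nor did ATF4 genes (5 higher and 12 lower of 26, 0.0572), the lipid droplet list (5 higher and 6 lower of 21, or 5 and 7 adjusted over the list alone, 0.991) or LXR targets (4 higher and 1 lower of 13, 0.464). The cell cycle list (12 higher and 2 lower of 25, or 13 and 2 adjusted over the list alone, 0.205) and p53 targets (3 higher and 7 lower of 16, or 5 and 7 adjusted over the list alone, 0.222) were not called, though CDKN1A of the latter fell 2.63-fold.

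In wild type SUM159 cells TXNIP rose 7.17-fold with glucose (16.3 ± 1.18 against 2.26 ± 0.0375 CPM, adjusted p = 6.11e-07, n = 3 against 3), and ARRDC4 was not called (adjusted p = 0.179). Genes chosen after their values were seen complete the count by edgeR of 3 higher and 2 lower. TTC17 rose 1.44-fold and the humanin-like MTRNR2L8, which resembles mitochondrial sequence, 1.34-fold. The neuropeptide receptor gene VIPR1 (log2 fold change −0.64) and the xenobiotic enzyme gene CYP1A1 (log2 fold change −1.27) fell. The count at an unadjusted p under 0.05 was 1495, DESeq2 called 135 genes higher and 20 lower, and quality weights, chosen after seeing the data, gave 772 and 472. Without any 1 library the higher count was 1, TXNIP, and the lower count was 0 except without WT 25 mM replicate 2, where it was 3. By adjusted p, TTC17 stood at 0.0996, 0.0843 and 0.122 without WT 0 mM replicates 1, 2 and 3 and at 0.0757, 0.0796 and 0.103 without WT 25 mM replicates 1, 2 and 3. MTRNR2L8 stood at 0.16, 0.213 and 0.225 without WT 0 mM replicates 1, 2 and 3 and at 0.104, 0.207 and 0.226 without WT 25 mM replicates 1, 2 and 3. VIPR1 stood at 0.0752, 0.0843 and 0.0676 without WT 0 mM replicates 1, 2 and 3 and at 0.0757 and 0.103 without WT 25 mM replicates 1 and 3. CYP1A1 stood at 0.0752, 0.106 and 0.0676 without WT 0 mM replicates 1, 2 and 3 and at 0.102 and 0.103 without WT 25 mM replicates 1 and 3. MTRNR2L8 was not called with the GC correction either (0.0886). With quality weights ARRDC4 was called (0.0127). ChREBP and MondoA targets shifted up with 1 of 14 called, or 3 adjusted over the list alone (camera adjusted p = 3.01e-05, 0.0202 with an estimated correlation). Mitochondrially encoded genes shifted up with 0 of 13 called (0.00027, 0.888 with an estimated correlation). Chaperones shifted up with 0 of 20 called, or 3 adjusted over the list alone (0.0174, 0.6 with an estimated correlation), the latter lost without WT 0 mM replicate 3 (0.309) or WT 25 mM replicate 1 (0.199) and with the GC correction (0.078).

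In the knockout cells glucose did not change TXNIP (log2 fold change −0.07 ± 0.24, adjusted p = 0.866). The interaction was called for this gene, whose response to glucose was 7.54-fold lower in KO than in WT cells (adjusted p = 0.00278). All 13 mitochondrially encoded genes rose, MT-ND1 by 1.64-fold (camera adjusted p = 4.21e-10, 0.886 with an estimated correlation). Their share of counts was 3.7% in KO 25 mM replicate 1 and 5.87% and 4.9% in replicates 2 and 3, against 3.08% to 3.4% in the KO libraries at 0 mM. Of the glycolysis genes, 12 of 22 fell, or 13 adjusted over the list alone (0.00149, 0.886 with an estimated correlation), SLC2A1 by 1.31-fold, and after correction for GC content and length this shift was not called (0.116). Ribosome biogenesis genes had 9 of 21 lower and 1 higher, or 10 and 1 adjusted over the list alone (0.0295, 0.886 with an estimated correlation), a call lost without KO 0 mM replicate 3 (0.149) or KO 25 mM replicate 1 (0.182). STC2, a secreted glycoprotein gene, fell 1.5-fold (adjusted p = 0.0053). With only these 6 libraries fitted, 0 genes were called by edgeR, with 4958 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0981, so none of the genes named here kept its call, where DESeq2 on all libraries called 4598. In all 1673 genes were higher and 2249 lower, but only 49 and 68 by at least 2-fold. They were 3682 and 3929 with quality weights and 501 and 415 with the GC correction. The counts were 2 and 3 without KO 0 mM replicate 2, 3419 and 3564 without KO 25 mM replicate 1, 2 and 6 without replicate 2 and 2 and 4 without replicate 3 of that group, and 1099 were lower without KO 0 mM replicate 1. Among the largest rises were pseudogenes, whose counts are uncertain because of their likeness to the parent genes, such as FTH1P2, at 26.3 CPM in KO 25 mM replicate 1 and 1319 and 1197 CPM in the other two. By adjusted p, MT-ND1, SLC2A1 and FTH1P2 each stood at 0.0975 without KO 0 mM replicate 2 and at 0.0919 and 0.104 without KO 25 mM replicates 2 and 3. SLC2A1 stood at 0.28 with the GC correction.

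The interaction in SUM159 cells had 0 genes higher and 2 lower by edgeR, with 2015 at an unadjusted p under 0.05 and 2 higher and 3 lower by DESeq2. With quality weights 1399 were higher and 2292 lower. Beside TXNIP, the read-through transcript SPECC1L-ADORA2A was called (adjusted p = 0.0361), which had 0 counts in the KO libraries at 25 mM, at least 10.2-fold below KO cells at 0 mM, and was named after its values were seen. The call of TXNIP held without any single library. By adjusted p, SPECC1L-ADORA2A stood at 0.102, 0.109 and 0.121 without WT 0 mM replicates 1, 2 and 3 and at 0.181 and 0.128 without WT 25 mM replicates 1 and 3. It stood at 0.0752 and 0.122 without KO 0 mM replicates 1 and 2 and at 0.075 and 0.112 without KO 25 mM replicates 2 and 3. Without KO 25 mM replicate 1 the interaction had 1381 genes higher and 2099 lower. Mitochondrially encoded genes shifted up (0 of 13 called, camera adjusted p = 9.99e-06, 0.782 with an estimated correlation).

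Loss of MLX in the carcinoma line and in macrophages was set side by side over 12913 genes tested in both. At 25 mM, 89 genes were lower in both, MLX among them, where 56 would be shared by independent lists (Fisher's exact test, one-sided, p = 5.85e-07). Higher in both were 16, where 11.2 would be (Fisher's exact test, p = 0.0772), among them FABP4 of the PPAR list. In opposite directions were 60 genes, where 62.4 would be. At 0 mM, 84 genes were lower in both (54.2 by independent lists, Fisher's exact p = 1.33e-05) and 24 higher (11.9, p = 0.000363), including the interferon-stimulated OASL, against 93 in opposite directions (63.9). The genes that moved together became 205 by DESeq2 and 175 with quality weights at 25 mM, and 189 with quality weights and 180 with the GC correction at 0 mM. Those in opposite directions became 121 and 104 at 25 mM, where 134 and 114 would be by independent lists. At 0 mM they became 137 and 164, where 127 and 128 would be. With the GC correction at 25 mM, 133 genes moved together and 111 apart, where 97.7 apart would be by independent lists. By edgeR, TXNIP was the only gene called in the same direction with glucose in control macrophages and WT SUM159 cells, and 1 gene moved in opposite directions. DESeq2 gave 21 genes in the same direction (17.3 higher and 2.56 lower by independent lists) and 48 in opposite directions (20.3). Quality weights gave 186 (118 and 74.5) and 305 (194), and the GC correction 2 and 1. By DESeq2 and with quality weights, more genes thus moved apart than together.

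**Figure D3:**
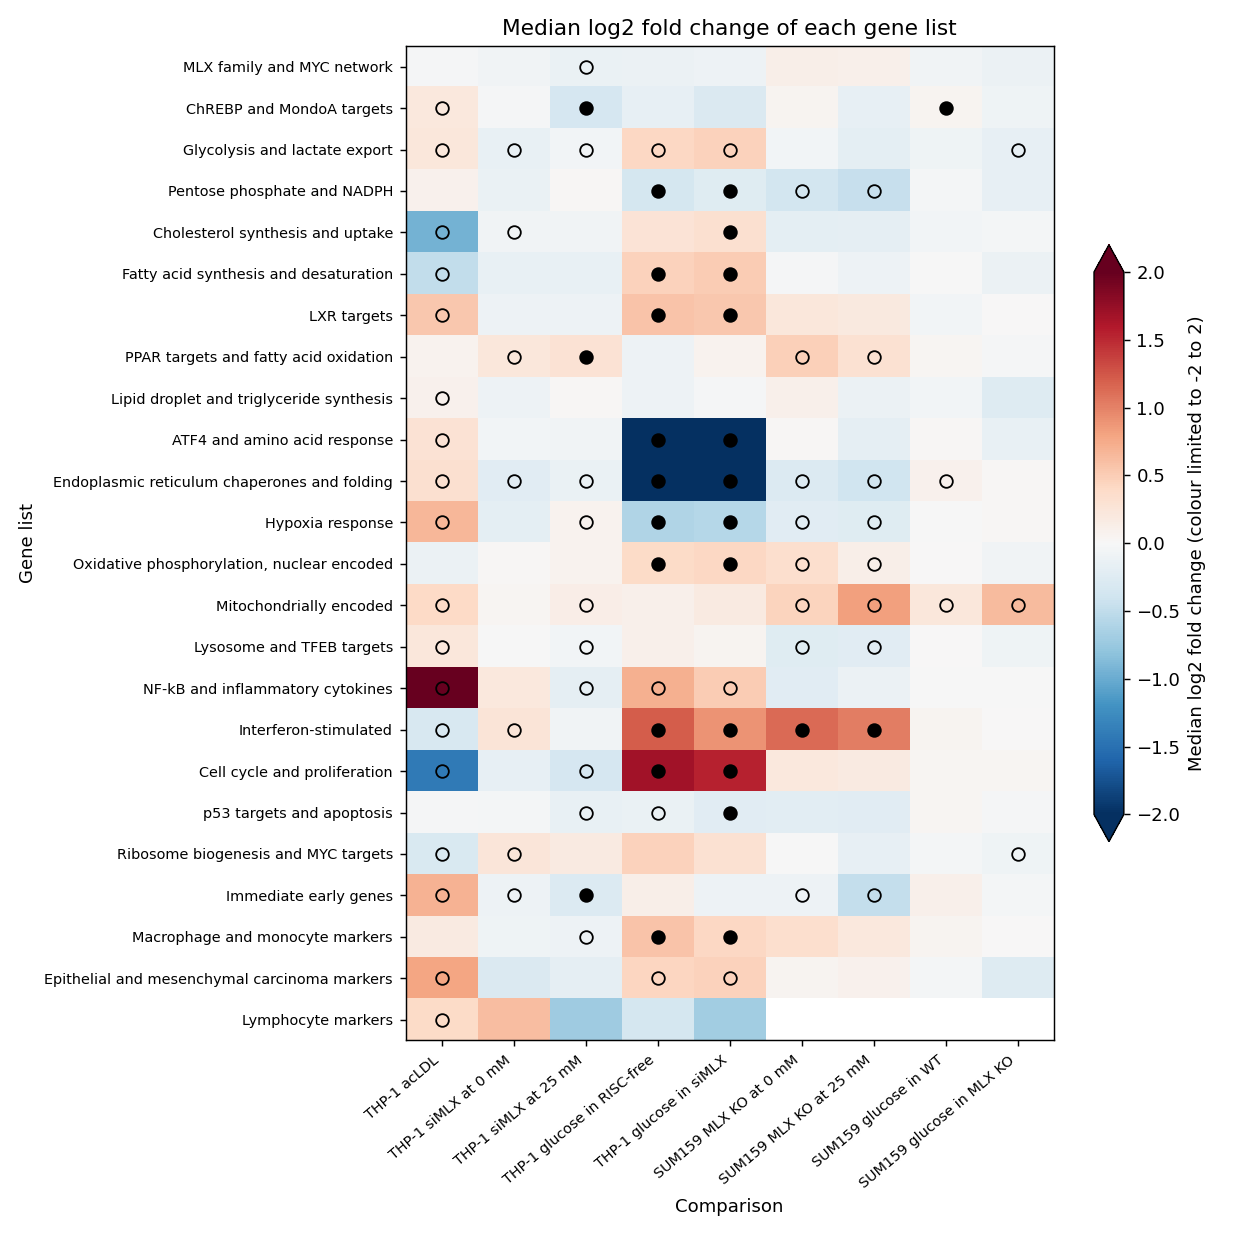
Median log2 fold change (colour) of 24 gene lists in 9 comparisons. Circles mark a camera adjusted p below 0.05 with the preset correlation, filled where it also held with an estimated correlation, and lymphocyte markers had fewer than 3 tested genes in SUM159. The chaperone and ATF4 lists have medians of −2.70 and −2.20 with glucose in control macrophages.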

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

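The slope of 1 knockout library on its group and the share of direction between knockout and siRNA calls were chosen only after the results were seen, as were the BCV of the arrangements, the quality weights and the GC correction. The results in this part are those in which the effect of glucose differed with MLX by a test of the difference itself.

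In macrophages, 5 genes differed by the interaction of siRNA and glucose: ADM2 (adjusted p = 0.00865), DTL (0.0366), SPP1 (0.0404), HSPA1B (0.0468) and OASL (0.0477). The 6th is not given here. None of the 5 kept its call without each single library in turn, with the values given beside the genes above. The lists with a different response to glucose by camera were interferon-stimulated genes (adjusted p = 2.79e-15), NF-kB and cytokine genes (4.55e-05), ChREBP and MondoA targets (0.00724), immediate early genes (0.0103) and, with a smaller fall in siMLX cells, the pentose phosphate list (0.0405). None of these lists was called with an estimated correlation (0.198 for the first 3 lists, 0.388 for immediate early genes and 0.255 for the pentose phosphate list). The ChREBP and MondoA list stood at 0.102 without siMLX 0 mM replicate 3. Immediate early genes stood at 0.0669 without RISC-free 0 mM replicate 3 and 0.0972 without siMLX 0 mM replicate 1. The pentose phosphate list stood at 0.0552 with RLE size factors, at 0.112 and 0.0521 without RISC-free 0 mM replicates 1 and 2, and at 0.0829 and 0.142 without RISC-free 25 mM replicates 2 and 3. It stood at 0.0972 and 0.0904 without siMLX 0 mM replicates 1 and 2, and at 0.0563 and 0.245 without siMLX 25 mM replicates 1 and 2. Of 100 arrangements of the labels, 7, the real one included, gave at least its 6 genes. Arrangements that keep the MLX labels whole at a glucose level carry the effect of siMLX at that level. Mixing the labels raised the BCV from 0.313 to a median of 0.343. The count therefore decides nothing about chance, which is not excluded. The highest other arrangement called 930 genes, which points to a structure of the samples, since it exchanged the MLX labels at 1 glucose level.

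In SUM159 cells, TXNIP (adjusted p = 0.00278) and SPECC1L-ADORA2A (0.0361) differed by the interaction, as did mitochondrially encoded genes (9.99e-06) and glycolysis (0.0434) by camera. With an estimated correlation both lists stood at 0.782. Glycolysis stood at 0.0591 with RLE size factors and 0.494 with the GC correction. It stood at 0.0629 and 0.078 without WT 0 mM replicates 1 and 3, at 0.0573, 0.057 and 0.0529 without WT 25 mM replicates 1, 2 and 3, at 0.0666 and 0.0605 without KO 0 mM replicates 2 and 3, and at 0.0699 and 0.0645 without KO 25 mM replicates 2 and 3. Of 100 arrangements, 3, the real one included, gave at least its 2 genes. The others mixed WT and KO libraries, which raised the BCV from 0.092 to a median of 0.245, so few of them could call genes and the count decides nothing about chance. The highest other called 7711, again with the MLX labels exchanged at 1 glucose level, which follows the large difference between the lines.

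For the other counts, 3 against 3 libraries make 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real splits called 458 and 313 genes with siMLX at 0 and 25 mM, 3392 and 3008 with glucose in control and siMLX macrophages, 4850 and 6969 in knockout cells at 0 and 25 mM and 5 with glucose in WT cells, against 0 in the highest other split by edgeR. With glucose in KO cells the real split called 3922 and the highest other 1. Every other split mixed libraries of the groups compared. This raised the BCV, from 0.092 to a median of 0.193 in knockout cells at 25 mM and from 0.313 to 0.33 with siMLX at 0 mM. Where the groups differ, such splits can call few genes, so these counts decide nothing about chance.

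The first pattern weighed is the many small changes with glucose in KO cells. Pseudogenes made up 3.4% of called genes against 8.4% of those tested. Only 1204 pseudogenes were tested, against 3922 genes called, so they could not have made up most calls. The count also misses shifts of their parent genes, so it does not decide on shared reads. A further pair of technical explanations stays open. Fold changes followed GC content (Spearman −0.63), and after correction 15.6% of the called genes, 605 of 3867, were still called in the same direction, while the median absolute log2 fold change of called genes fell from 0.38 to 0.16. Replicate 1 at 25 mM moved only 0.121 to 0.211 of the shift of the other 2, which could come from cells kept at 0 mM in that library. WT 25 mM replicate 1 also stood apart, with a quality weight of 0.376 against 1.637 and 1.451 for WT 25 mM replicates 2 and 3. Its residuals correlated with those of KO 25 mM replicate 1 at 0.158, the highest of such pairs. What these libraries share was not tested. A response of KO cells to glucose stays open as well, because a correction for GC content may also remove biology that follows GC content.

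The second pattern is the wide spread between replicates of the siRNA experiment, with a BCV of 0.313 against 0.092 in SUM159. SUM159 libraries thinned to the median depth of the siRNA libraries had a BCV of 0.086, so sampling fewer counts did not raise the estimate. The BCV is meant to leave counting error out, so thinning could hardly have shown otherwise and decides little about depth. Leaving out any 1 library left the BCV of the siRNA experiment at 0.313 or more, up to 0.348. The filter on low counts was run again each time with a smaller group, which can let in more low-count genes. Such genes had a higher BCV, so a fall could be hidden and this decides little about a single deviating library. The BCV of genes at 100 CPM or more was 0.174 of that of genes at 1 to 10 CPM (0.101 against 0.579), where the ratio was 0.482 in SUM159 and 0.435 in the acLDL experiment. Few starting molecules may therefore explain the spread, and no biological explanation was tested.

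The third pattern is the large number of calls in KO cells. A difference between the lines other than MLX cannot be told apart from the loss of MLX, because the labels do not say how many knockout clones were used. Among genes called in both, siMLX and KO shared direction for 53.7% of 201 at 0 mM (Fisher's exact p = 0.115) and 63.6% of 165 at 25 mM (Fisher's exact p = 0.0491). MLX, targeted in both experiments, is counted among the genes that shared direction, and the second p is close to the threshold. At 25 mM the fold changes of both comparisons followed GC content (Spearman −0.24 with siMLX and −0.35 in KO cells). With the GC correction, 133 genes moved together at 25 mM (29 higher and 104 lower, where 26.7 and 74.3 would by independent lists). Apart moved 111, where 97.7 would. A shared trend over GC content is therefore not excluded as a source of shared direction. Only 2.5% and 1.67% of KO calls were shared in direction with siMLX, but the cell types differ and siMLX had fewer calls, so this does not separate the explanations. Loss of MLX stays open as the biological explanation.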

How the results depend on the processing

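Quality weights and the GC correction were chosen after seeing the data. The MLX level kept its direction and its side of the threshold in 126 of 131 alternative values, and 103 of 300 alternative counts of genes moved by over 1.5 times, with RLE size factors moving none of 22. The cause was not tested except where fewer genes or libraries were fitted. Of 98 list calls, 28 held with an estimated correlation, 88 with the GC correction, 95 with a replicate block and 94 with RLE, and 534 of 594 without 1 library. Of the named genes put through these alternatives, none reversed. MRC1, GNLY, NKG7 and TGFBI with acLDL were not among them. DESeq2 gave no adjusted p for TXNIP with glucose in WT cells. Where a left-out library leaves 1 sample in a group (acLDL), that sample is assumed to vary like the other groups.

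With DESeq2, counts were 206 higher and 547 lower for siMLX at 0 mM, 151 and 500 at 25 mM, 15 and 32 for the THP-1 interaction, 135 and 20 for glucose in WT cells, and 2 higher for the SUM159 interaction. Overlaps, as genes in the same direction here and below, were 288 for siMLX at 0 and 25 mM, 205 for siMLX and KO at 25 mM, 21 for glucose in RISC-free and WT, 106 for glucose in WT and KO, and 129 for acLDL and siMLX. With no filter, counts were 100 higher for siMLX at 25 mM, 9 and 12 for the THP-1 interaction, 12 and 5 for glucose in WT and 3 higher for the SUM159 interaction, with overlaps of 7 (glucose in WT and KO) and 92 (acLDL and siMLX). With only the 6 libraries, they were 27 higher for siMLX at 25 mM, 22 and 9 for glucose in WT, and 0 and 0 by edgeR for glucose in KO (4958 at an unadjusted p under 0.05, and 4598 by DESeq2 on all libraries).

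With quality weights, counts were 191 higher for siMLX at 0 mM, 1 higher for the THP-1 interaction, 772 and 472 for glucose in WT, 3682 and 3929 for glucose in KO and 1399 and 2292 for the SUM159 interaction. Overlaps were 189 and 175 for siMLX and KO at 0 and 25 mM, 186 for glucose in RISC-free and WT, 880 for glucose in WT and KO and 98 for acLDL and siMLX. Fold changes followed GC content at a Spearman correlation of 0.13 with acLDL, −0.01 and −0.24 with siMLX at 0 and 25 mM, 0.05 and −0.1 with glucose in control and siMLX macrophages, and −0.19 for the THP-1 interaction. In SUM159 it was −0.07 and −0.35 in KO cells at 0 and 25 mM, −0.36 and −0.63 with glucose in WT and KO, and −0.49 for the interaction. With the GC correction, counts were 272 and 131 higher for siMLX at 0 and 25 mM, 5 lower for the THP-1 interaction and 501 and 415 for glucose in KO. Overlaps were 180 for siMLX and KO at 0 mM, 2 for glucose in RISC-free and WT and 119 for acLDL and siMLX. Of the lists, 1 was called in the SUM159 interaction with the GC correction or RLE. MLX rose with glucose in siMLX cells with weights (log2 fold change 1.06) and with the GC correction (0.91).

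With the replicate block, counts were 35 higher for siMLX at 25 mM, 1 and 1 for each interaction, 4 lists for siMLX at 0 mM, and MLX rose with glucose in siMLX cells (0.99). The lists lost at 0 mM were glycolysis, cholesterol and immediate early genes, each at a camera adjusted p of 0.0559. Of the interaction genes, HSPA1B (edgeR adjusted p = 0.114), OASL (0.136), DTL (0.0528) and SPECC1L-ADORA2A (0.195) were not called. Residuals of libraries with the same number correlated at −0.009 in the acLDL, −0.082 to 0.06 in the siRNA and −0.107 to 0.158 in the knockout experiment. The highest, 0.158, was between WT and KO replicates 1 at 25 mM, so the numbers pair the libraries weakly at most. With an estimated correlation, lists called were 0 with acLDL, 0 and 3 with siMLX, 0 for the THP-1 interaction, 1 and 1 in KO cells, 1 with glucose in WT, 0 with glucose in KO and 0 for the SUM159 interaction.

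Without 1 library, counts ranged from 43 to 77 higher and 211 to 266 lower for siMLX at 0 mM, 18 to 47 and 155 to 262 at 25 mM, 0 to 3 and 0 to 2 for the THP-1 interaction, 1 to 1 and 0 to 3 for glucose in WT, 2 to 3419 and 3 to 3564 for glucose in KO, and 0 to 1381 and 1 to 2099 for the SUM159 interaction. MLX with glucose ranged from 0.57 to 1.78 in siMLX cells and its interaction from 0.55 to 1.76, the highest without siMLX 0 mM replicate 1. Lists called ranged from 3 to 6 for the THP-1 and 1 to 3 for the SUM159 interaction.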

Other observations

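The overlap of lipid loading with loss of MLX was fixed before its values were seen, and more genes moved apart than together. Per the labels, cells were differentiated for 1 day in the acLDL and 2 days in the siRNA experiment. Among 14601 genes tested in both, 26 rose with acLDL and with siMLX at 25 mM, where 12.2 would by independent lists (Fisher's exact p = 3.46e-05), PLIN2 among them. In both, 35 fell, LIPA among them, where 57.9 would, and 163 moved in opposite directions, where 69.3 would. The 61 that moved together became 129 by DESeq2, 92 with no filter, 98 with quality weights and 119 with the GC correction, against 270, 198, 213 and 216 in opposite directions. PLIN2 rose 2.01-fold with acLDL and 1.5-fold with siMLX, and LIPA fell 2.23-fold and 2.31-fold. EGR1 moved apart, 3.91-fold higher with acLDL and 2.54-fold lower with siMLX, as did APOE, 2.49-fold higher and 1.67-fold lower, and VEGFA, 3.6-fold higher and 1.68-fold lower.

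Marker lists of other cell types were tested in macrophages. With acLDL, 2 of 6 lymphocyte markers rose, or 3 adjusted over the list alone, GNLY 2.97-fold and NKG7 2.48-fold (camera adjusted p = 0.0191, 0.188 with an estimated correlation, and 0.0722 without no-acLDL replicate 2). The carcinoma markers had 6 of 13 higher with acLDL, or 7 adjusted over the list alone (0.00261, 0.168 with an estimated correlation), TGFBI 2.12-fold. With glucose they had 2 of 12 higher and 2 lower in control macrophages (0.0462, 0.295 with an estimated correlation), where the median (0.44) and mean (−0.25) differed in sign. This call was lost with RLE size factors (0.0508), with the GC correction (0.0811) and without RISC-free 0 mM replicate 1 (0.218), RISC-free 25 mM replicate 1 (0.0711) or RISC-free 25 mM replicate 2 (0.0683). In siMLX macrophages 3 of 12 rose with glucose (0.0353, 0.292 with an estimated correlation), a call lost without siMLX 0 mM replicate 2 (0.0828) or siMLX 25 mM replicate 1 (0.0824). In SUM159 macrophage markers had 1 of 4 higher and 1 lower in KO cells at 0 mM (0.594).

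Mitochondrially encoded genes took 2.37 ± 0.123% and 2.73 ± 0.104% of counts in WT cells at 0 and 25 mM, and 3.25 ± 0.16% and 4.82 ± 1.09% in KO cells, where replicate 1 at 25 mM stood at 3.7% and the other two at 5.87% and 4.9%.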
